A study of Mus musculus with 2 samples.

How the data were processed

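H3K9me3 ChIP-seq was measured in 2 biological replicates of newborn (0 day) mouse hindbrain, sexes pooled. Per the labels, fragments were of 300 to 500 bp, replicate 1 combined 2 technical replicates and 15 mice, and replicate 2 combined 3 technical replicates of pooled mice. The groups and replicate numbers were taken from the labels. The deposited files were 4 peak lists in narrowPeak format. Per the description deposited with the files, the coordinates are mm10, the list of each replicate derives from its filtered alignments and 2 further files, the pooled list from both replicates' alignments and the same further files, and the replicated list from the other 3 lists. The aligner, the peak caller and its threshold are not given in the sources used here.

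The enrichment of each peak is the signal value deposited by the authors, a ratio with no unit. What it is a fold over is not stated beyond the format. The −log10 p and −log10 q of each peak are also the authors' values, deposited in the same lists. The smallest −log10 p in the replicates' lists was 2.06 and 2.03, so the lists hold weak peaks: 36.4% of replicate 1 peaks and 52.6% of replicate 2 peaks had a q under 0.05. These values were used to describe, rank or filter peaks within a list. The files hold no read counts, so depth is unknown and no interval that needs depth is given. Wilson intervals of shares of peaks cover counting of peaks only.

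Coordinates were compared with the GRCm38.p6 reference genome, whose main chromosomes are those of mm10. On the 21 main chromosomes (19 autosomes, X and Y) 0 peaks extended past a chromosome end. Genes, transcripts and exons came from the GENCODE M21 basic annotation. Peaks on unplaced or unlocalised contigs (316, 257, 269 and 207 in the replicate 1, replicate 2, pooled and replicated lists) entered the descriptions of the 4 lists, the comparison of the replicated list with the others and the correlation of enrichment between replicates, and were left out of the tests of placement. Coordinates are printed counting from 1.

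Sharing between replicates meant an overlap of at least 1 bp. It was compared with 1000 circular shifts of the replicate 2 peaks along the part of each chromosome without N, which keep peak lengths and spacing. Promoters were the 1 kb on either side of a transcription start site, and each peak was placed by its summit as promoter, exon, intron or intergenic, in that order. Features and sequence composition were compared with 1000 circular shifts of the replicated peaks (two-sided), features with Benjamini-Hochberg adjustment over the 4 classes. Soft-masked bases were those in lower case in the reference. Domains chained peaks closer than 10 kb and were compared with 1000 random placements of the peaks on their chromosome.

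Before the data were examined, 16 gene lists were fixed: zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, imprinted, germline, housekeeping, neuronal, hindbrain patterning, forebrain and midbrain patterning, glial, non-neural lineage, X-linked testis, tandem secreted and immune, and heterochromatin regulator genes. The share of each list whose gene body met a replicated peak was compared with 10000 random lists of protein-coding genes of the same size, drawn from the same 20 bins of gene length. The two-sided empirical p was adjusted by Benjamini-Hochberg over the 16 lists, and 0.000533 is the smallest value reached. Adjusted values are over the lists. Non-coding imprinted genes were counted apart. For zinc finger genes, a peak in the last exon of the transcript with the longest span was set against a peak at the start site by an exact McNemar test, and genes with and without another member within 100 kb were compared by Fisher's exact test.

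The genes named were chosen by a rule fixed before the data were examined. It took the 15 protein-coding genes whose body held the replicated peak with the highest enrichment among those met by each replicate (16 with ties), up to 4 members of each list by that value or all members where 6 or fewer were met, the genes of the 10 longest domains by base pairs in peaks, and the members met of any list below its random lists. The value printed for a gene is the mean ± SD over the replicates of the highest replicate peak that overlaps the gene's strongest replicated peak. Where a replicate has no such peak, no value is given.

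The list test and the overlap test were tested on simulated peaks before use. Peaks were placed at random and a random list was drawn from the 21911 genes. With no added peaks 1 of 20 such lists was called at 0.05. With a peak added to each member at a chance of 10% 19 of 20 were called, and with 20% or 40% all 20 were. These rates were not measured separately by list size. They thus do not show how often such an excess would be called in short lists, such as the glial (30 genes) or germline (49 genes) list. Neither peaks in clusters nor lists of tandem genes were simulated, so the rate of false calls for such lists was not measured. The overlap test called 0 of 10 simulated pairs without copied peaks and 10 of 10 with 5% of the peaks copied from replicate 1, over 40661 peaks.

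Alternatives changed a single choice each, except for replicate 1's own list on autosomes only, which changed both the list and the chromosomes. Those on autosomes only (except for the overlap), the peak counts at a −log10 p of at least 5 and the named genes in other lists were chosen after seeing the data. They were a −log10 p of at least 5, the pooled list, each replicate's own list in place of the replicated list (leaving out the other replicate), other overlap rules (50% of the peak or of both peaks, the latter with 100 shifts), equal numbers of peaks, random placement, autosomes only, promoters of 2.5 kb, a flank of 5 kb, at least 500 bp of peak, circular shifts for the lists, a single member per 100 kb, the last 2 kb of a gene, neighbours within 50 kb, domain gaps of 1 and 50 kb, and pooled peaks outside the replicated list as background. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.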

Results

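Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of constitutive heterochromatin and of silenced gene clusters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse hindbrain on the day of birth. The hindbrain gives rise to the cerebellum, pons and medulla. The data held 1 group with 2 biological replicates, each made from pooled male and female animals. Replicate 1 came from 15 mice and 2 technical replicates, and replicate 2 from a pool of mice, their number not given in the labels, and 3 technical replicates. The measurements were 4 lists of peaks in mm10 coordinates, 1 for each replicate, 1 called on the replicates together (the pooled list) and 1 of peaks retained as replicated. The peak lists held no read counts, so the sequencing depth behind each peak is unknown. The enrichment of a peak is the authors' value, a ratio, and is used here only to describe and rank peaks. With 1 group there was no contrast between conditions, and the comparisons were between the replicates and between the peaks and their genomic background.

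The 2 replicates marked the same places far more often than chance, although most peaks of each were not shared. Replicate 1 held 40977 peaks over 11.5 Mb and replicate 2 held 36800 peaks over 10.5 Mb, a mean of 38890 ± 2954 peaks (SD, n = 2). On the assembled chromosomes 27.9% of replicate 1 peaks shared at least 1 bp with a replicate 2 peak, against a mean of 0.895% after circular shifts of the peaks along each chromosome, and 31.3% of replicate 2 peaks were shared, against 1.00%. The base-pair Jaccard index was 0.138, against 0.00252 after shifting. Each value exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest the shifts can give). The shared percentage was higher at higher −log10 p. That value does not follow enrichment alone: a replicated peak among the highest by it (chr17:39843083-39846756) had an enrichment of 1.86. Among peaks with a −log10 p from 3 to 4 it was 18.6% in replicate 1 and 21.2% in replicate 2 (95% Wilson intervals 17.9 to 19.2 and 20.3 to 22.1). Among peaks at 10 or above it was 90.2% of 325 peaks and 85.7% of 525 peaks (intervals 86.4 to 92.9 and 82.5 to 88.45). The number of peaks per replicate changed order with the threshold: at a −log10 p of 5 or more, replicate 1 kept 9373 peaks and replicate 2 kept 12416.

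**Figure D1:**
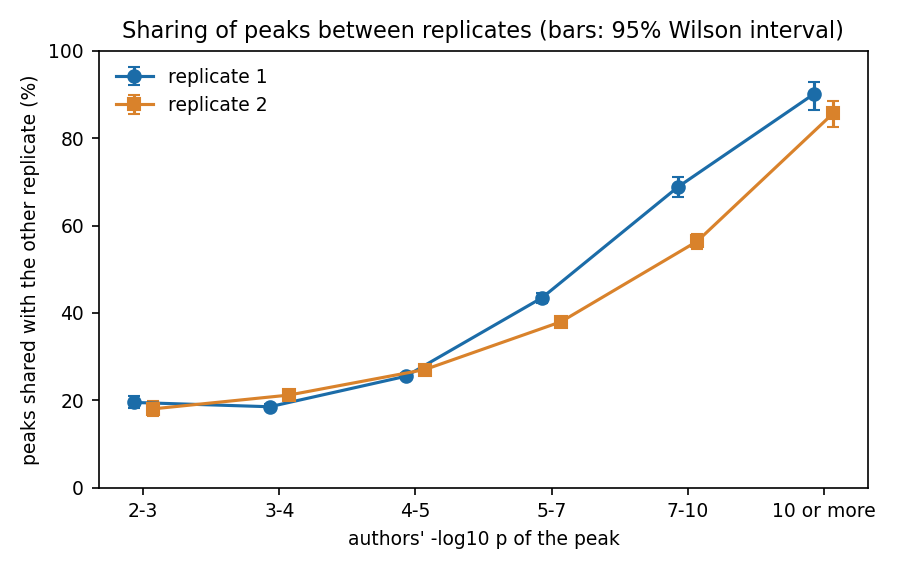
Percentage of each replicate's peaks that share at least 1 bp with a peak of the other replicate (vertical axis) by the authors' −log10 p of the peak (horizontal axis), with 95% Wilson intervals. The percentage stays near 20% at the lowest −log10 p and reaches 90.2% in replicate 1 and 85.7% in replicate 2 at 10 or above.

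The replicated list held 13674 peaks with a median length of 383 bp and a median enrichment of 3.13, and covered 6.38 Mb. All of them were identical in position and enrichment to a pooled peak, and they made up 37.7% of the 36309 pooled peaks. Of the replicated peaks, 77.1% met a peak of each replicate and 37 met a peak of neither. At the 10541 peaks met in both, the median enrichment was 3.16 in replicate 1 and 3.31 in replicate 2. Across those peaks the log2 enrichment of the replicates correlated with a Pearson r of 0.286 and a Spearman rho of 0.232. Peaks are not independent replicates, so no p is attached to these correlations. Among peaks with a −log10 p of at least 5 the correlations fell to 0.175 and 0.0897. That filter narrows the range of enrichment, which by itself can lower a correlation. The fall thus does not show that stronger peaks agree less.

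The clustered protocadherin genes had the highest share of genes with H3K9me3 of the 16 gene lists tested. These genes encode cell-surface adhesion proteins whose stochastic promoter choice gives neurons distinct surface identities, and they lie in 3 arrays on chromosome 18. A replicated peak met 52 of 56 gene bodies (92.9%), against 16.8% in random lists of protein-coding genes matched on gene length, and each replicate's own, longer list met 92.9% as well, against 38.8% (replicate 1) and 32.5% (replicate 2) in its own random lists. This included 12 of 13 alpha genes, all 22 beta genes and 18 of 21 gamma genes. The 4 genes without a peak, named after their values were seen, were Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5. Peaks also lay near the transcription start sites: 49 of the 56 genes (87.5%) had one within 1 kb. Peaks were dense along the arrays, so this does not show a preference for start sites. The gamma array (chr18:37661793-37841873) was 49.0% covered by 82 replicated peaks, the beta array (chr18:37264938-37524479) 28.85% by 121 and the alpha array (chr18:36930184-37187661) 18.2% by 75. The strongest of these peaks, at chr18:37731592-37732708, overlapped the promoter of Pcdhgb5 and introns of upstream gamma genes such as Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhga4, and reached an enrichment of 7.07 ± 0.434 (SD, n = 2 replicates). It tied those genes, the other gamma genes from Pcdhga5 to Pcdhga8, Pcdhgb1, Pcdhgb2, Pcdhgb4 and 3 predicted genes that span several arrays (Gm37013, Gm37388 and Gm42416) among the coding genes with the highest enrichment. The list passed the test at an adjusted permutation p of 0.000533, and the gene bodies of the alpha and gamma arrays share peaks because they are nested, while those of the beta array are separate except for Pcdhb21 and Pcdhb22.

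**Figure D2:**
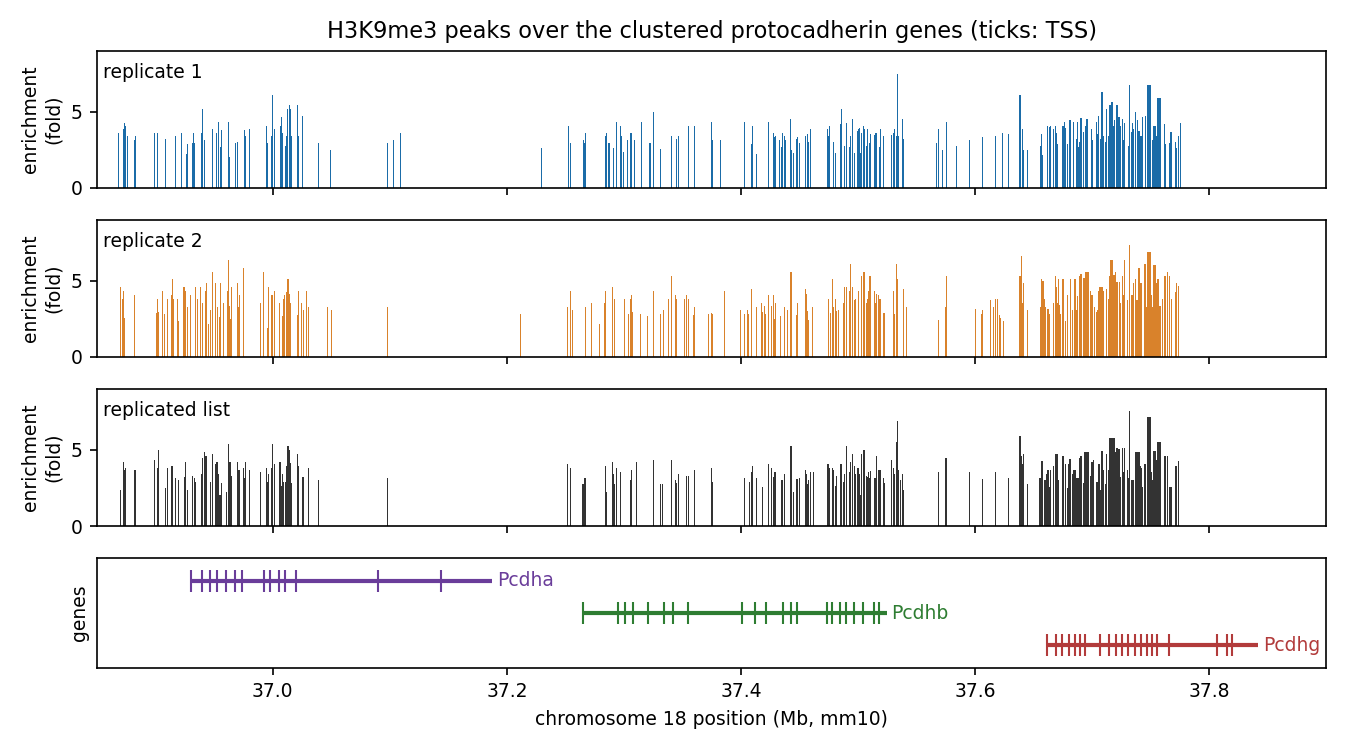
Peaks of replicate 1, replicate 2 and the replicated list across the clustered protocadherin genes on chromosome 18, each drawn as a bar from its start to its end at its enrichment (fold, vertical axis), with position in Mb (mm10) on the horizontal axis. Below, lines span the alpha, beta and gamma arrays and ticks mark transcription start sites. Replicated peaks cover 49.0% of the gamma array, 28.85% of the beta array and 18.2% of the alpha array.

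Zinc finger genes, many of which encode DNA-binding repressors, were marked at their 3′ ends. A replicated peak met 119 of 422 genes of the list (28.2%, against 6.69% in matched random lists, adjusted permutation p = 0.000533), and the replicates' own lists met 40.5% ± 2.68 (SD, n = 2), against 17.4% (replicate 1) and 13.2% (replicate 2) in their own random lists. The last exon, which commonly encodes the fingers, held a peak in 90 genes (21.3%) and the 1 kb either side of the start site in 1 gene (0.237%). No gene had both, and the difference was tested across discordant genes by an exact McNemar test (two-sided p = 7.43e-26). With the start site in place of the gene body, the list no longer exceeded its random lists (0.237% against 0.851%, adjusted permutation p = 0.487). The coding gene with the highest enrichment of all was Zfp180 on chromosome 7. Its peak at chr7:24103854-24108325 covered the last exon and had an enrichment of 8.50 ± 1.94 (SD, n = 2). By the enrichment in the replicated list, by which genes were ranked, Zfp981 came next in the zinc finger list (6.90), and Zfp606, Zfp329 and Zfp945 tied after it (6.02). Over the replicates Zfp981 had 6.79 ± 0.7765 at an intronic peak (chr4:146533980-146534530), Zfp606 with 5.89 ± 0.671 in the last exon (chr7:12493094-12495081) and Zfp329 with 5.50 ± 0.518 in an exon (chr7:12809758-12811581). Genes with another list member within 100 kb were marked more often than lone genes, 80 of 245 (32.7%) against 39 of 177 (22.0%), an odds ratio of 1.72 (Fisher's exact test, two-sided p = 0.0211). Genes of a cluster are not independent, so this p and that of the McNemar test may be too small. The groups of Fisher's test were not matched on gene length. Chromosome 7 held the most members of the list, of which 24 of 104 were met, and no difference between chromosomes was tested.

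Vomeronasal receptor genes, the pheromone receptors of the vomeronasal organ, were met in 77 of 326 cases (23.6%, against 4.31% in random lists). The receptors of the Vmn2r family were met in 43 of 120 genes (35.8%) and those of the Vmn1r family in 34 of 206 (16.5%). Examples were Vmn1r224 (enrichment 3.83 ± 0.0122, SD, n = 2, peak at chr17:20423887-20424190 in the last exon), Vmn1r81 (4.16 ± 0.491), Vmn2r104 (3.95 ± 0.168) and Vmn2r60 (3.92 ± 1.17, with 20 peaks in the gene body). The tandem families of secreted and immune proteins were met in 50 of 437 genes (11.4%, against 4.03%). Among these were Skint5 (4.08 ± 0.348, with 71 peaks), Skint2 (4.08 ± 0.348, 20 peaks) and Skint9 (4.08 ± 0.348, 11 peaks), members of a family of immunoglobulin-like proteins of skin and thymus on chromosome 4, and Ceacam14 (4.29 ± 0.311) on chromosome 7. Both lists passed the test at an adjusted permutation p of 0.000533. Olfactory receptor genes were met in 69 of 1134 cases (6.09%, against 2.93%, adjusted permutation p = 0.000533). Chromosome 2 held the most members of the list, of which 19 of 294 were met. Examples were Olfr398 (4.26 ± 0.0883), Olfr872 (4.05 ± 0.331), Olfr347 (4.00 ± 1.19) and Olfr943 (3.95 ± 0.168). The olfactory list did not pass when the peaks were circularly shifted in place of drawing random genes (adjusted permutation p = 0.291), a test that keeps the clustering of peaks.

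Imprinted genes, which are expressed from the allele of a single parent, were met in 19 of 40 coding cases (47.5%, against 13.03%, adjusted permutation p = 0.000533), and the replicates' own lists met 66.25% ± 12.37 (SD, n = 2), against 30.8% (replicate 1) and 25.4% (replicate 2) in their own random lists. A replicated peak lay within 1 kb of the start site in 9 of them. The strongest was at Klf14 (chr6:30956285-30958686, promoter, enrichment 5.43 ± 0.506). Trappc9, the host gene of Peg13, had 3.815 ± 0.346 at an intronic peak (chr15:72721695-72722289), Kcnq1 3.855 ± 0.667 at an intronic peak that also lies in Kcnq1ot1 (chr7:143250273-143251318) and Snrpn 3.57 ± 0.635 at an intronic peak (chr7:60002984-60003320). Of 6 non-coding imprinted genes annotated, Kcnq1ot1, Peg13 and Airn were met. Germline genes, which somatic tissues keep silent, were met in 8 of 49 cases (16.3%, against 8.25%) and did not pass (adjusted permutation p = 0.152). They included Tdrd9 (3.68 ± 0.532, intron), Meioc (3.46 ± 0.213, intron), Ddx4 (3.75 ± 0.462, promoter) and Mael (3.23 ± 0.106, promoter). Taken at the start site, 4 of 49 had a peak (8.16%, against 1.04%) and the list passed (adjusted permutation p = 0.00747), as it did with the pooled list (38.8% against 16.5%, adjusted permutation p = 0.000914) and with replicate 1's own list (36.7% against 22.3%, adjusted permutation p = 0.0434). It did not pass with replicate 2's own list (28.6% against 17.0%, adjusted permutation p = 0.0848), nor with replicate 1's own list on autosomes only (34.8% against 21.1%, adjusted permutation p = 0.0704).

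**Figure D3:**
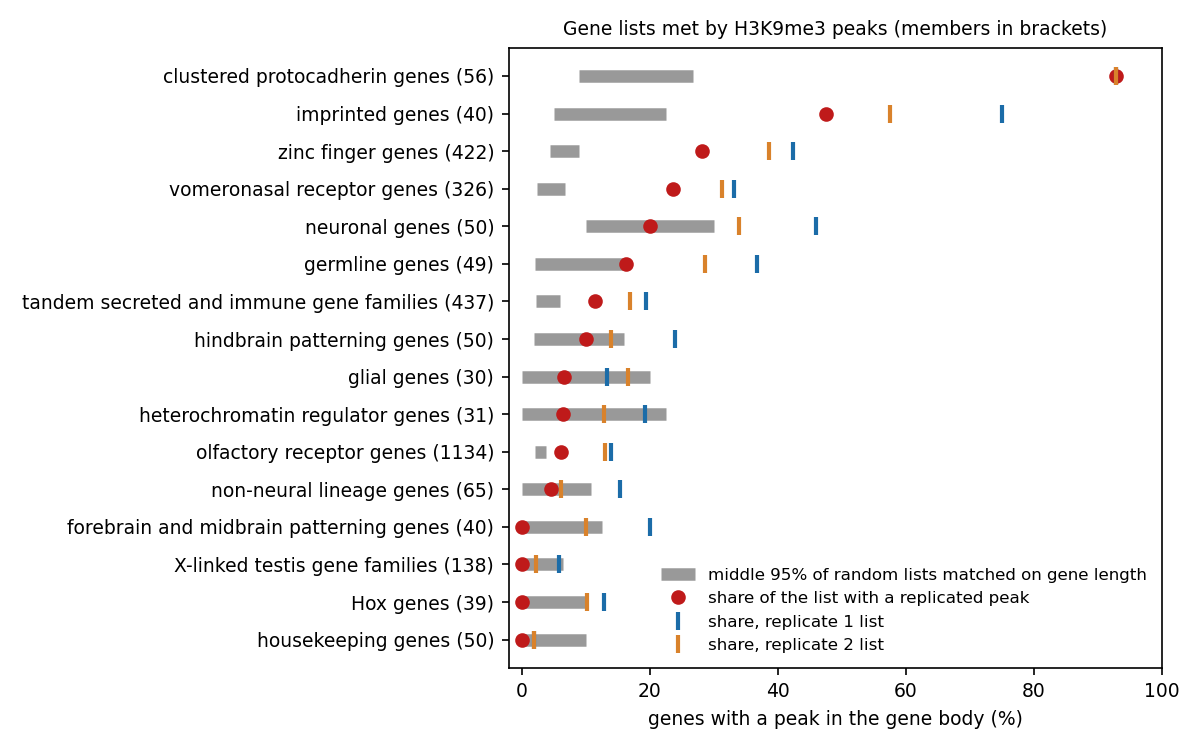
Percentage of each gene list whose gene body meets a replicated peak (red points, horizontal axis) with the middle 95% of random lists matched on gene length (grey bars) and the percentages in each replicate's own, longer list (blue and orange ticks). The grey bars apply to the red points. The protocadherin, imprinted, zinc finger and vomeronasal lists lie far to the right of their grey bars.

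The lists of neural identity and general function were not called different from their random lists. Neuronal genes were met in 10 of 50 cases (20.0%, against 20.5%, adjusted permutation p = 1.0), among them Rbfox1 (3.31 ± 0.722), Nrxn1 (3.76 ± 1.17) and Gria1 (3.25 ± 0.446), all long genes of synapses or splicing in neurons, and the sodium channel gene Scn8a. Hindbrain patterning genes were met in 5 of 50 cases (10%, against 8.06%, adjusted permutation p = 0.877): Pax5 (3.12 ± 0.266), Rora (2.88 ± 0.201), Pax3 (3.03 ± 0.499), Foxp2 (3.24 ± 1.17) and Tph2 (3.08 ± 0.115), each with its strongest peak in an intron. No gene was met among 39 Hox genes (3.57% in random lists, adjusted permutation p = 0.708), 50 housekeeping genes (4.13%, p = 0.367) and 40 forebrain and midbrain patterning genes (5.14%, p = 0.367). Their random lists held a mean of 1.39, 2.07 and 2.06 genes met, and 0, the lowest possible count, could not be called below that. The test thus could not show a depletion of these lists. In the pooled list the housekeeping genes did lie below their random lists. Glial genes were met at Cx3cr1 and Nfib (2 of 30, against 10.2%, adjusted permutation p = 0.877), non-neural lineage genes at Cyp3a11, Cps1 and Nphs2 (3 of 65, 4.62% against 4.59%, p = 1.0) and genes of heterochromatin regulators at Smchd1 and Atf7ip (2 of 31, 6.45% against 10.4%, p = 0.877). The X-linked testis gene families, a list that also holds 6 autosomal genes, were met in 0 of 138 cases, below their random lists (3.49%, adjusted permutation p = 0.0288). That call did not hold with circular shifts, which keep the low peak density of the X (0.955%, adjusted permutation p = 0.639), nor in either replicate's own list. Over all 16 lists, 6 lay above and 1 below their random lists. Among all 21911 protein-coding genes 1880 were met (8.58%). These p-values describe where the peaks of these lists lie, not the spread between animals, and genes of a cluster are not independent.

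Peaks gathered in domains. Chaining replicated peaks closer than 10 kb gave 7086 domains, of which 414 held 5 or more peaks. Those 414 held 38.1% of the peaks, against 0.0510% when peaks were placed at random on their chromosome (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Each peak was placed on its own, so pieces of a broad region cut apart by a narrow peak list also exceed these placements. The test does not tell such pieces from separate sites. The number of domains with 5 or more peaks was 169 with a gap of 1 kb, 242 with 50 kb and 801 in the pooled list. The domain with the most base pairs in peaks lay over the protocadherin gamma genes (chr18:37655113-37775530, 88 peaks, 93.3 kb, 77.5% covered). The second, with 146 peaks and 78.4 kb, lay over Ceacam11, Ceacam12, Ceacam13, Igfl3 and Gm5155 (chr7:17884572-18187722). The third (chr18:36893465-37039402, 56.4 kb) and the sixth (chr18:37473321-37542916, 35.9 kb) lay over the alpha genes and over Pcdhb15 to Pcdhb22. The fourth (chr1:88211427-88257746) lay over the Ugt1a genes, which encode glucuronosyltransferases of drug and bilirubin clearance, and over Mroh2a. It held 13 wide peaks that covered 89.1% of it, 91.6% in replicate 1 and 81.0% in replicate 2. The fifth (chr4:121975495-122059898, 50 peaks) held a processed pseudogene and no protein-coding gene. The seventh (chr12:114332035-114463072, 56 peaks) and ninth (chr12:114110586-114229208, 48 peaks) lay over immunoglobulin heavy chain variable segments. The eighth (chr2:76709425-76767682, 34 peaks) lay in Ttn, the giant protein of striated muscle, and the tenth (chr13:61527233-61636123, 47 peaks) over Ctsm, Gm49352 and Cts3, cathepsin genes of the placenta and a predicted gene.

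Chromosomes differed in peak density. Chromosome 7 held 16.1 replicated peaks per Mb, 3.485 times the autosomal median of 4.62, followed by chromosome 17 with 11.2 and chromosome 4 with 8.31. These 3 chromosomes held 34.0% of the replicated peaks. In the replicates' own lists chromosome 7 held 36.7 and 32.3 peaks per Mb. The X held 0.881 replicated peaks per Mb and the Y 0.0681. Both sexes were pooled, so the X and the Y are at lower copy number than the autosomes, and mappability was not tested. These densities thus do not show that the sex chromosomes carry less of the mark. The replicates disagreed on the X: replicate 1 had 2728 X peaks and replicate 2 had 390, a ratio of 6.995, while the 19 autosomal ratios lay between 0.972 and 1.14. Only 96 of the 2728 X peaks of replicate 1 were shared, and 113 of the 390 of replicate 2. At a −log10 p of at least 5 the X ratio was 3.71 and the autosomal ratios lay between 0.586 and 0.852. No test was made between chromosomes.

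**Figure D4:**
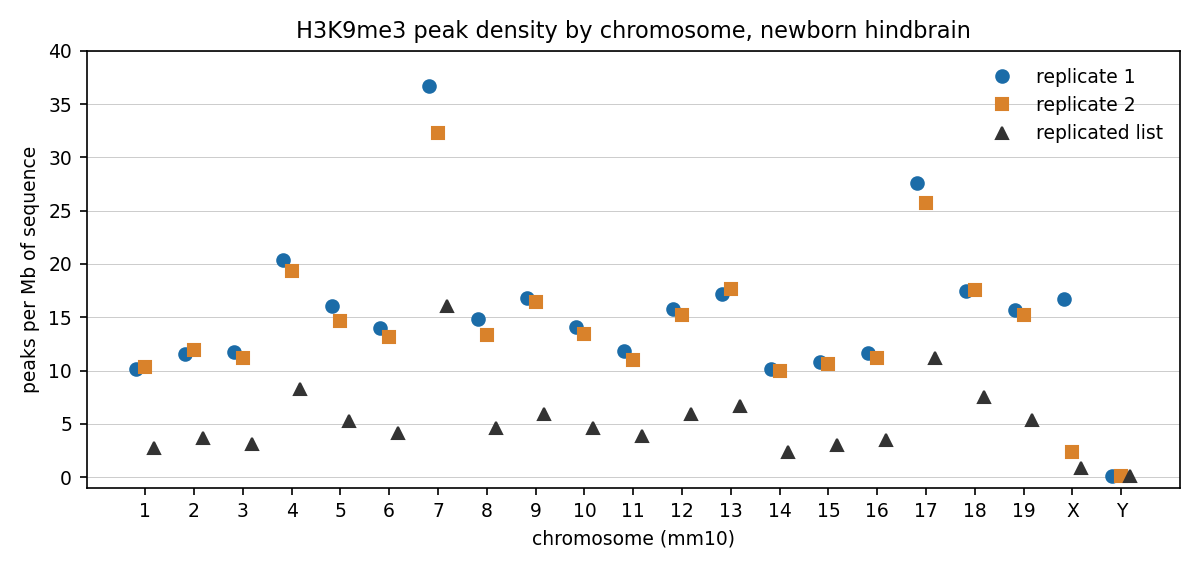
Peaks per Mb of sequence (vertical axis) on each mm10 chromosome (horizontal axis) in replicate 1 (circles), replicate 2 (squares) and the replicated list (triangles). The replicates lie close together on every autosome, highest on chromosome 7 at 36.7 and 32.3, and apart on the X at 16.7 and 2.385.

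Replicated peaks lay outside genes more often than shifted peaks, and among peaks in genes they lay more often at promoters and exons. By summit, 57.0% were intergenic (49.8% after circular shifts), 29.8% intronic (42.1%), 7.63% within 1 kb of a start site (4.83%) and 5.58% in other exons (3.255%), each at the smallest adjusted permutation p the shifts can give (two-sided, 0.002). In the replicates' own lists the promoter share was 6.01% ± 0.560 and the intergenic share 58.85% ± 0.623 (SD, n = 2). With pooled peaks outside the replicated list as the background, the intergenic share was lower, not higher (57.0% against 60.1%, Fisher's exact test, adjusted p = 1.08e-08). The sequence under replicated peaks was 43.8% G and C, against 42.1% after shifts, and 23.6% soft-masked as repeats, against 33.9% (two-sided permutation p = 0.002 each, the smallest the shifts can give). The shifts land on all sequence without N, including repeats where reads may not be placed uniquely. Mappability was not tested, so the lower soft-masked share does not show that the mark avoids repeats.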

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

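The tests of peak yield on the X and of the clustering of X peaks were chosen only after the result was seen, as were the values for contigs and the use of sharing on autosomes alone, a value chosen before the data were examined, to test an explanation. For the X, the predictions of a higher dose and of discrete sites were both met as written, and the resampling interval and the thinning that leave them open were added after that was seen. The design names no biological group, so no difference between groups was tested as an explanation. Discrete heterochromatin sites on the X were tested, and for the patterns not on the X no biological explanation was tested.

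Signal appeared outside the main chromosomes, in peaks that the tests of overlap, features, composition, gene lists and domains leave out, although they enter the descriptions of the lists and the correlation of enrichment between replicates. Unplaced or unlocalised contigs held 207 replicated peaks (1.51%) on 21 contigs, 52 of them on 1 contig. Their median −log10 p was 11.8, against 5.63 on the main chromosomes, while the median enrichment was 3.16 against 3.13. Of the 100 replicated peaks with the highest −log10 p, 42 lay on contigs. The cause was not tested.

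Replicate 1 had 2728 X peaks and replicate 2 had 390. The X density of replicate 1 (16.7 per Mb) lay within its autosomal range (10.1 to 36.7). That of replicate 2 (2.385) lay below its own range (9.99 to 32.3), and a loss of X peaks in replicate 2 was not tested. At a −log10 p of at least 5 lay 12.8% of the X peaks of replicate 1, against 23.2% of its autosomal peaks. In replicate 2 these were 24.1% and 33.5%. A higher yield of replicate 1 on every chromosome is argued against, since the X ratio of 6.995 lay above all 19 autosomal ratios (0.972 to 1.14). A higher X dose in replicate 1 relative to its control stays open, and was tested only at X peaks that replicate 2 also met. The median log2 ratio of enrichment at 89 replicated X peaks was -0.059, above the highest autosomal median of -0.079, as had been predicted, but its resampling interval (-0.12 to 0.032) includes that median. Discrete sites seen in replicate 1 alone also stay open. The variance-to-mean ratio of the unshared X peaks of replicate 1 over 1 Mb bins was 11.55, above the autosomal median of 9.59. That met a prediction written after the X peak counts were seen, but the ratio was 7.98 after thinning to 1752 peaks.

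Most peaks of each replicate were not shared. The X peaks of replicate 1 are too few to be the source, at 2728 of its 40661 peaks on the main chromosomes. For the same reason the share on autosomes alone (29.6%, against 27.9% over all main chromosomes) had little room to differ and adds nothing as a test. Peaks near the detection threshold may account for part of it, since sharing was higher at higher −log10 p. The prediction of at least 90% sharing in both replicates at a −log10 p of 10 or above was missed by replicate 2 (85.7%) and met by replicate 1 (90.2%), so the extent cannot be told. Depth was unknown, so a difference in depth was not tested.

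Nearly every clustered protocadherin gene held a replicated peak. Nested gene bodies that share the same peaks are argued against as the only source. Of the genes, 87.5% had a peak within 1 kb of the start site, and the highest of 10000 random lists reached 10.7%. Those lists scatter genes over the genome, while these start sites lie in arrays dense in peaks. The comparison thus does not show that start sites themselves are preferred. A high peak density over the whole of chromosome 18 is argued against too: 0 of 1000 circular shifts reached the observed 92.9%, with a highest value of 82.1% and a mean of 19.06%. The arrays themselves hold 75 (alpha), 121 (beta) and 82 (gamma) of the 657 replicated peaks on that chromosome. Shifting moves this block off these genes, so a lower share was likely beforehand. The shifts show only that the density elsewhere on the chromosome does not give such a share. Reads shared between these paralogs were not tested and stay open.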

How the results depend on the processing

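The autosome-only tests of gene lists, features, zinc finger genes and domains, the peak counts at a −log10 p of at least 5 and the named genes in other lists were chosen only after the result was seen. Of 289 alternative values, named genes left out, 232 kept their direction and side of the threshold or moved little, and 57 did not. Of 173 alternative values of named genes, 118 moved little and 55 did not. Of the 50 coding genes with the highest enrichment, 35 were shared without replicate 1, 41 without replicate 2 and all 50 in the pooled list. Every replicated peak is also a pooled peak with the same enrichment. Agreement with the pooled list was thus largely set beforehand, for the named genes as well, and is no separate check. Gamma protocadherin genes that share their strongest peak are not separate cases. Replicate overlap, sequence composition, zinc finger gene ends and clustered zinc finger genes kept their calls under all alternatives run. For the changes below the cause was not tested. No paired analysis was possible because the design has 1 group.

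With a −log10 p of at least 5, the peak ratio of replicate 1 to replicate 2 turned to 0.755 and the X ratio fell to 3.71. The correlations fell to a Pearson r of 0.175 and a Spearman rho of 0.0897, non-neural genes turned below random (3.08%), the X-linked testis call ended (0%), leaving 0 lists below, and chromosome 7 reached 3.55 times the autosomal median. With the mean of overlapping peaks the correlations were 0.237 and 0.1925.

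In the pooled list, germline (38.8%) and housekeeping genes (0%) passed, 2 lists lay below, hindbrain (14%) turned below and forebrain and midbrain genes (10%) above random. The densities of chromosomes 7, 17 and 4 were 2.83, 2.16 and 1.53 times the median, and 801 domains held 5 or more peaks, against 414 in the replicated list. In the replicated list that number was 169 with a gap of 1 kb and 242 with 50 kb. Against pooled peaks outside the replicated list, the intergenic share (57.0%) turned below its background (60.1%).

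Without replicate 1 or without replicate 2, Hox genes turned above random (10.3 to 12.8%) and 0 lists lay below. The ranges were 14 to 24.0% for hindbrain genes, below random without replicate 1, and 6.15 to 15.4% for non-neural genes, likewise. They were 34.0 to 46.0% for neuronal and 10 to 20.0% for forebrain and midbrain genes, both above random without replicate 2. Germline genes (28.6 to 36.7%) passed without replicate 2 and X-linked testis genes (2.17 to 5.80%) passed in neither.

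With 5 kb flanks non-neural genes turned below random (6.15%). At the start site zinc finger (0.237%) and hindbrain genes (0%) turned below and forebrain and midbrain genes (2.5%) above, germline genes passed (8.16%), the X-linked testis call ended (0%) and 0 lists lay below. With at least 500 bp of peak neuronal genes turned above (14%), non-neural genes below (1.54%), the X-linked testis call ended (0%) and 0 lists lay below. With circular shifts the olfactory (6.09%; adjusted p over its alternatives up to 0.291) and X-linked testis calls (0%) ended, non-neural genes turned below (4.615%) and 0 lists lay below. With 1 member per 100 kb the X-linked testis call ended (0%) and 0 lists lay below. On autosomes only, non-neural genes turned below (4.69%), the X-linked testis call ended (0% of the 6 autosomal genes of that list) and 0 lists lay below. In replicate 1 on autosomes only, Hox (12.8%), forebrain and midbrain genes (20.5%) and the 6 autosomal genes of the X-linked testis list (16.7%) turned above random, and 0 lists lay below. Depth is unknown, so what it limits could not be given.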

Other observations

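All tests in this part were chosen only after the main results were seen.

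Of 234 families of at least 10 protein-coding genes that share a symbol stem, outside the 16 lists, 2 lay above their random lists and 0 below. Secretoglobin (Scgb) genes were met in 8 of 33 cases (24.2%, against 2.22%, adjusted permutation p = 0.0234). Nlrp genes were met in 9 of 17 cases (52.9%, against 9.435%, adjusted permutation p = 0.0234). All members met in these families lie on chromosome 7. Circular shifts were run for these 2 families alone and gave an unadjusted permutation p of 0.0240 for Scgb and 0.0040 for Nlrp, so they do not show that either family would pass over all 234.

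Among 19 annotated gene types, of which those named here were chosen after their values were seen, immunoglobulin V genes were met in 22 of 218 cases (10.1%, against 1.44%) and immunoglobulin V pseudogenes in 18 of 158 (11.4%, against 1.39%), each at an adjusted permutation p of 0.000633. These segments lie in tandem and share domains of peaks, and circular shifts, which keep the clustering of peaks, were not run for the gene types. T cell receptor V genes were met in 0 of 144 cases (1.39% in random lists, adjusted permutation p = 0.373). Other types passed at an adjusted permutation p of 0.00543 or less. Transcribed unprocessed pseudogenes (11.5%, against 5.36%), other unprocessed pseudogenes (4.35%, against 2.25%) and long intergenic non-coding RNA genes (6.17%, against 5.32%) lay above. Genes of the annotation type TEC (0.559%, against 1.69%) and protein-coding genes (8.57%, against 9.01%) lay below.

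The first 1 Mb of sequence at the centromere end was denser in replicated peaks than the rest of the chromosome on 9 of 19 autosomes (exact binomial p = 1.0, two-sided), with 0 to 56 peaks. The median over the autosomes was 8.0 peaks there and 4.49 per Mb in the rest. The sign count does not weigh the size of a difference, which was largest on chromosomes 3 (56 peaks, against 2.82 per Mb in the rest) and 16 (52 peaks, against 2.94). The other end was denser on 7 of 19 (exact binomial p = 0.359).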
